A study of Mus musculus with 6 samples.

How the data were processed

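Gene expression was measured by 10x Genomics Chromium 3' single-cell RNA sequencing in 6 libraries of mouse bone marrow HSCs, 1 library per group, each from pooled mice. Per the file headers, the deposited matrices were written by Cell Ranger 7.2.0 and hold whole UMI counts per gene and barcode. The genome build is mm10, per the submitters' processing notes. No gene annotation version, cell call or normalization is recorded. The deposited counts are unfiltered: each file lists 32285 genes and 2806918 to 3475555 barcodes. Gene symbols and Ensembl identifiers were taken from the deposited feature tables, and 32158 of the 32285 identifiers (99.6%) were found in GENCODE mouse M21 (GRCm38), from which gene positions and overlaps were read for the 306 named genes.

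Groups were read from the sample titles, treatment labels and design note. The DMSO library was assigned to young mice because the design note says so, although its title reads old-like and the extraction protocol names old cells. The untreated library was the control for both drugs, since it matches them in age and culture time by its labels. The protocol names a DMSO control, but the label of this library gives no treatment. The drug ratios may therefore also hold a vehicle difference. The DMSO library was tried as the other control.

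Barcodes were kept with at least 1000 UMIs, at least 10% of the 99th percentile of the 6000 richest barcodes, at least 500 genes and at most 20% mitochondrial UMIs. The resulting floor was 3322, 3531, 2507, 7564, 1426 and 3456 UMIs in young fresh, old fresh, DMSO, untreated, ConA and ddC. Kept barcodes held 40.9%, 42.5%, 45.5%, 78.1%, 57.7% and 41.6% of all UMIs in that order, or 67.7, 123.3, 76.8, 76.9, 80.6 and 56.3 M (mega) UMIs. With 56.3 to 123.3 M kept UMIs per library, a floor of 3 counts stood for 0.0243 to 0.0533 CPM.

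UMIs were summed over kept barcodes per library and scaled to CPM over all genes. The log2 ratio of CPM plus 1 was computed for genes with at least 10 CPM in either library of a comparison, and genes at least 2-fold apart were counted. Fold differences are ratios of CPM without the added 1. Their 95% intervals are exact conditional binomial intervals, those of CPM exact Poisson and those of cluster shares exact binomial, and all cover counting error only. Where a library had 0 UMIs, the fold is a bound computed with 3 counts in that library in place of 0, and not an end of the 95% interval.

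In all, 7 comparisons were made: old over young fresh, ConA and ddC each over untreated, untreated over old fresh, DMSO over young fresh, untreated over DMSO, and ConA over ddC. With 1 library per group no test, p-value or standard error was computed. For 44 gene lists with 711 entries (4 entries, Aldoa, Ddit3, Mx1 and Mx2, had no unique gene in the files), the median log2 ratio of members was set against 10000 random lists of the same size matched on mean expression in 20 bins. Lists with at least 3 measured members were used, and members at least 1.5-fold apart were counted. Pearson's r and Spearman's rho of log2 ratios were computed for 5 pairs of comparisons across the 8441 genes with a mean of at least 10 CPM over the 6 libraries. For ConA and ddC, which share a control, 20 simulations of unchanged groups were drawn with counting error only.

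Genes named in the text are the 8 highest and 8 lowest log2 ratios for old over young fresh, ConA and ddC, and the 5 highest and 5 lowest for the other comparisons, among genes with at least 10 CPM in the higher library. Unnamed gene models and mitochondrial and ribosomal protein genes were left out of this ranking. Of each list that stood apart, up to 4 members with the largest ratio in the direction of the median were added, of which the text gives leading ones. A few genes that met these rules are not printed.

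Kept barcodes of all libraries were clustered together with scanpy 1.11.5 (scaling to 10000 UMIs, 2000 variable genes, 30 principal components, 15 neighbours) and leidenalg 0.10.2 at resolution 0.6. Clusters were named where at least 3 markers of a cell type were among the 10 leading genes. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

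The ratio and list steps were tested on simulated data with known answers for each comparison. Apart from the changes set, the simulated ratios held counting noise only, and genes of the simulated lists shifted independently. The rates below therefore check the calculation. They do not give the rate of false calls between real libraries, which also differ in other ways. For old over young fresh, 99 of 100 genes made 3-fold different were counted among 8312 genes, as were 0 of 100 made 1.5-fold different and 0 of 8115 unchanged genes, and 95.0% of intervals held the true ratio. In the other comparisons 98 to 100 of the 100 genes made 3-fold different were counted. All 20 shifted lists were called in each comparison, and 2 to 9 of 100 unchanged lists.

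Choices of barcodes, scaling, lists, comparisons and named genes, and most alternatives, were made before the data were examined. The alternatives were other UMI floors, mitochondrial limits of 10% and none, totals without mitochondrial and ribosomal protein genes, median-of-ratios scaling, the mean of CPM per barcode, barcodes thinned to 1526 UMIs, pseudocounts of 0.1 and 5 CPM, minimums of 50 and 1 CPM, the DMSO library as control and cluster resolutions of 0.3 and 1.0. A further 3 were added after seeing the data: all barcodes summed, barcodes of at least 10000 UMIs, and kept barcodes without the megakaryocyte-like, granulocyte-like and stress-gene clusters.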

Results

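Hematopoietic stem cells (HSCs) were profiled by droplet single-cell RNA sequencing in 6 libraries, 1 for each of 6 groups of pooled mice. The cells were bone marrow cells sorted as lineage-negative, Sca1-positive, c-Kit-positive, CD150-positive and CD48-negative. Fresh HSCs came from mice of 8 weeks (young) or 20 months (old). Old HSCs were also cultured for 16 h without a drug, with 40 nM concanamycin A (ConA), which blocks the vacuolar proton pump that acidifies lysosomes, or with 40 µM dideoxycytidine (ddC), which blocks replication of mitochondrial DNA. The last library held HSCs cultured for 16 h and labelled DMSO. Its title calls it old-like, the design note states that its cells came from young mice without drug, and the extraction protocol speaks of old cells for every cultured sample. It is treated here as young, as in the design note.

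The libraries held 98.5 to 289.8 M (mega) UMIs (unique molecular identifiers, each counting 1 captured transcript). Per library the total was 165.7 M in young fresh, 289.8 M in old fresh, 168.8 M in DMSO, 98.5 M in untreated, 139.6 M in ConA and 135.5 M in ddC. Kept barcodes numbered 10077, 21349, 17485, 2723, 30780 and 7859 in that order, with medians of 4726, 4763, 3571, 23351, 2130 and 5089 UMIs. Labels gave 12000 to 16000 sorted cells per sample. The untreated library stood apart from the other 5, with 1.90% of its UMIs in barcodes of 500 to 10000 UMIs against 75.7% to 90.5% elsewhere. Barcodes of at least 500 UMIs numbered 3413 in untreated and 55723 to 110719 in the other 5, where they outnumbered the sorted cells. A kept barcode is therefore not read as 1 cell, and values are sums over the kept barcodes of a library in counts per M (CPM).

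**Figure D1:**
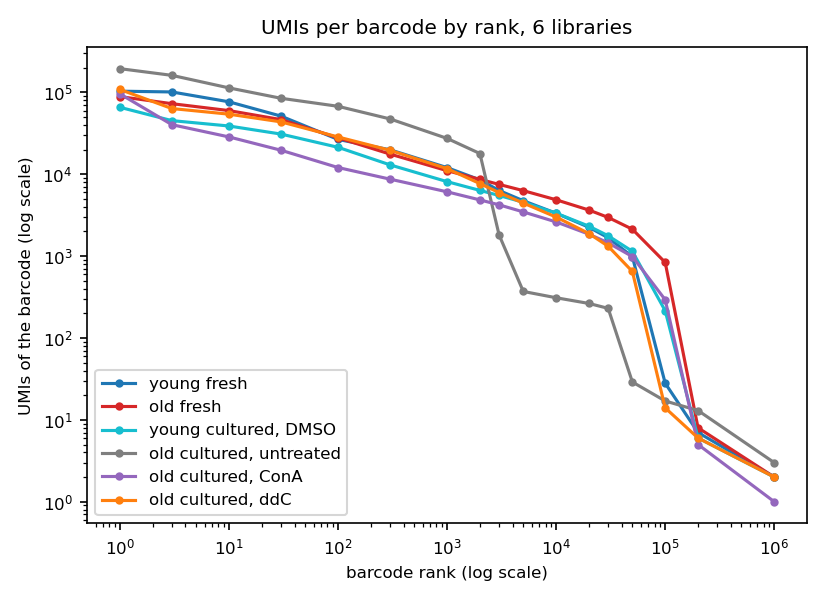
UMIs of a barcode (log axis) against the rank of the barcode by UMIs (log axis), 1 line per library. The untreated old cultured library drops steeply between ranks 2000 and 5000, and the other 5 libraries decline slowly to about rank 50000 and drop steeply only at higher ranks.

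Every group held 1 library, so no difference below has a replicate check and no test across samples was possible. Brackets after a fold difference give its exact 95% interval, which covers counting error only. A gene list is said to stand apart where the median of its members lay outside the central 95% of 10000 random lists matched on size and mean expression, and its percentile among those lists is given.

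The comparison of old fresh with young fresh HSCs asked what age changes in cells taken straight from the animal. Genes of the HSC ageing list, known from the literature to be higher in aged HSCs, were higher in the old library: 31 of 34 measured members were at least 1.5-fold higher and 0 were lower. Their median log2 ratio was 1.54 (percentile 100). Among them, Rorb, a nuclear receptor, was 35.6-fold (28.7 to 44.8) higher at 43.7 against 1.23 CPM. Sbspon, a secreted thrombospondin-domain protein, was 29.7-fold (23.2 to 38.5) higher, Plscr2, a phospholipid scramblase, 14.8-fold (13.2 to 16.5), and Nupr1, a stress-induced transcriptional regulator, 7.43-fold (7.09 to 7.79). Class II antigen presentation genes were also higher (5 of 6 members, median 1.90, percentile 100), with H2-Eb1 6.88-fold (6.46 to 7.32) and Cd74, the invariant chain, 5.35-fold (5.17 to 5.53) higher.

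Rorb lies on chromosome 19 (18930605 to 19111196, minus strand, GRCm38) and Sbspon on chromosome 1 (15853862 to 15892722, minus strand). Other genes with the highest ratios were Mab21l2 at 15.5 against 0.0886 CPM, Gpr183, an oxysterol receptor, at 31.4 against 0.709 CPM, Chrm3, a muscarinic acetylcholine receptor, at 18.9 against 0.576 CPM, and Eya4 at 22.2 against 1.15 CPM. The immunoglobulin heavy chain gene Ighm stood at 52.1 against 1.79 CPM, whereas Ighg1 had 0 UMIs in the old library against 47.8 CPM in the young, at least 1962-fold lower if 3 UMIs are taken for 0, as in all such bounds. In the old fresh library, 204 barcodes were rich in immunoglobulin transcripts.

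Granulocyte markers were lower in old fresh HSCs (4 of 6 members at least 1.5-fold lower, median -1.78, percentile 0). Among these, the neutrophil granule genes Mpo, Elane and Ctsg were 12.4-fold (10.96 to 14.0), 10.9-fold (9.80 to 12.3) and 8.29-fold (7.38 to 9.34) lower, and S100a8 was 1.95-fold lower. The eosinophil granule gene Prg2 was 123-fold (82.2 to 192) lower and Plac8 6.01-fold (5.76 to 6.28) lower. A cluster of barcodes with granulocyte genes held 2.71% of kept barcodes in young fresh and 0.276% in old fresh, and without it and 2 further clusters the granulocyte list median was 0.64 and S100a8 stood at 0.46.

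Cholesterol synthesis genes were lower in old fresh HSCs (6 of 21 members at least 1.5-fold lower, median -0.47, percentile 0). Among them, Cyp51 was 1.71-fold (1.62 to 1.79), Fdps 1.70-fold and Hmgcs1 1.63-fold lower. Genes of DNA replication (median -0.39, percentile 0, 5 of 23 lower) included the licensing factor Cdt1, 1.64-fold lower, and Hells, 1.56-fold lower. Ribosome biogenesis and Myc targets had a median of -0.29 (percentile 0), with Srm 1.39-fold lower. Mitosis genes had a median of -0.23 (percentile 0.01), with Mki67 1.304-fold lower, and all 21 members lay within 1.5-fold. Without 3 clusters of barcodes the mitosis and replication medians were larger in size, as given in the closing section. Integrated stress response genes (-0.19, percentile 1.80) included Phgdh, an enzyme of serine synthesis, 1.96-fold lower. Glycolysis genes (-0.17, percentile 1.55) included Aldoc, 1.65-fold lower. Histone genes Hist1h2ap and Hist2h2aa1 were 5.71-fold (5.64 to 5.77) and 6.70-fold (6.25 to 7.19) lower.

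Interferon response genes had a median of 0.19 in old over young fresh (percentile 100), with 8 of 29 members higher, 2 lower, and the GTPase Iigp1 2.70-fold (2.61 to 2.79) higher. Class I antigen presentation genes had a median of 0.42 (percentile 100), with B2m 1.41-fold higher. Smaller medians above the random lists were those of quiescence genes (0.31, percentile 100, with Txnip 1.89-fold higher), megakaryocyte markers (0.31, percentile 99.98, with Gp1bb 1.92-fold higher) and cytokine signalling targets (0.24, percentile 99.9, with Id2 2.51-fold higher). HSC markers had a median of 0.13 (percentile 99.7), with Procr, an HSC surface receptor, 1.79-fold and Hoxb5 1.97-fold higher. Mitochondrially encoded mRNA had a median of 0.13 and a mean of -0.048 (percentile 99.9). Autophagy genes (0.053, percentile 98.5) and cytoplasmic ribosomal proteins (0.054, percentile 99.1) had all members within 1.5-fold. Lysosomal hydrolases (-0.016), lysosomal membrane proteins (0.009) and subunits of the vacuolar proton pump, or V-ATPase (0.019), did not stand apart.

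In all, 124 genes were at least 2-fold higher and 59 at least 2-fold lower in old fresh among the 8498 with at least 10 CPM in either library, and 94.4% lay within 1.5-fold. The medians of autophagy, mitosis, cytoplasmic ribosomal proteins and interferon genes changed sign under at least 1 other setting, given in the closing section.

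**Figure D2:**
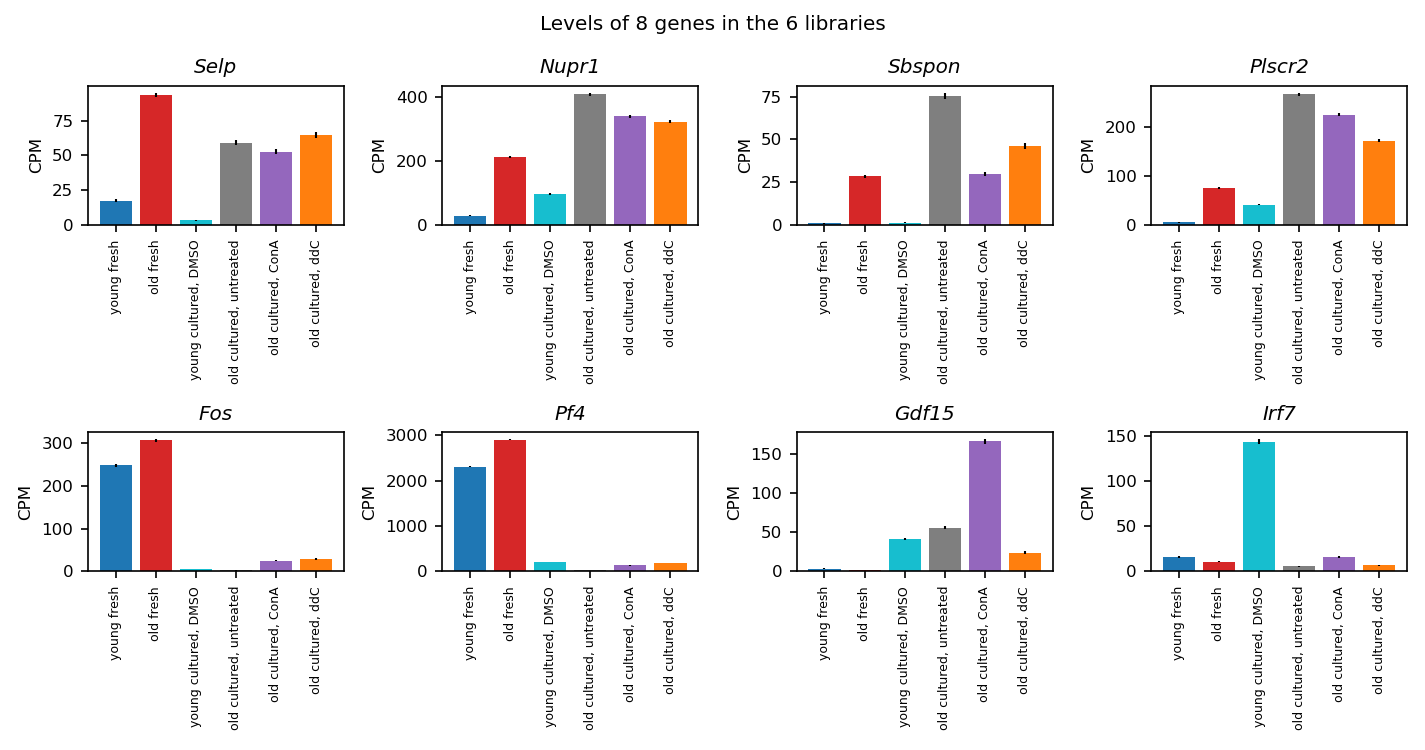
CPM of 8 genes named below and above (1 panel per gene, vertical axes from 0) in the 6 libraries, with exact Poisson 95% intervals as error bars that cover counting error only. Sbspon stood at 28.5 CPM in old fresh and 75.5 in old cultured untreated against 0.960 in young fresh, and Irf7 at 143.7 CPM in the DMSO library.

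The ConA comparison asked how old cultured HSCs differ when lysosomal acidification is blocked, with the untreated library as control. The protocol names a DMSO control, but the label of this library gives no treatment. Vehicle may therefore differ between each drug and this control. The untreated library stood apart from all others in how its UMIs were spread over barcodes. Barcodes of at least 10000 UMIs held 77.6% of its UMIs, against 2.2% with ConA and 16.5% with ddC. A drug effect and this difference between libraries can therefore not be told apart in either drug comparison. Comparisons of the untreated library with old fresh and with DMSO carry the same limit. Immediate early genes were higher with ConA (8 of 10 members at least 1.5-fold higher, median 1.69, percentile 100). Egr1 stood at 516 against 48.6 CPM, 10.6-fold (10.3 to 10.98) higher, Fos was 12.2-fold (10.4 to 14.5) higher, and Dusp1 and Ier2 were 4.59-fold and 3.71-fold higher. Cholesterol synthesis genes were higher (17 of 24 members, median 0.87, percentile 100), with the sterol sensor partner Insig1 3.33-fold (3.23 to 3.43) and Hmgcs1 2.50-fold (2.44 to 2.56) higher. NF-kB targets were higher too (9 of 11 members, median 0.92, percentile 100), with Nfkbiz 3.89-fold (3.50 to 4.33), Nfkb2 3.44-fold and Relb 3.06-fold higher. Of p53 targets, 7 of 14 were higher (median 0.64, percentile 99.99), including the cell cycle inhibitor Cdkn1a, 2.90-fold (2.79 to 3.01) higher, and Phlda3, 2.43-fold higher.

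Among lysosomal groups, membrane proteins had a median of 0.36 (percentile 99.7, 5 of 17 higher), with Cd68 1.99-fold (1.86 to 2.13) and the amino acid sensor Slc38a9 1.69-fold (1.59 to 1.79) higher. The membrane protein median was smaller among genes of at least 50 CPM and against the DMSO library, as given in the closing section. Autophagy genes had a median of 0.38 (percentile 99.96, 7 of 24 higher), with the receptors Optn 2.25-fold (2.05 to 2.47) and Sqstm1 1.71-fold (1.66 to 1.77) higher and Wipi1 1.83-fold higher. Hydrolases (0.16) and V-ATPase subunits (0.039) did not stand apart. Interferon response genes were higher (16 of 30 members, median 0.63, percentile 100), with Irf7 2.88-fold, Ifit1 2.39-fold and Isg15 2.33-fold higher.

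With ConA, replication genes had a median of -0.61 (12 of 23 members lower, percentile 0), with the helicase subunits Mcm5 and Mcm2 2.56-fold (2.41 to 2.71) and 1.95-fold (1.83 to 2.06) lower. The replication median was smaller in size for the mean of CPM per barcode and for thinned barcodes, as given in the closing section. Ribosome biogenesis and Myc targets had a median of -0.56 (9 of 21 lower, percentile 0), with Myc itself 2.61-fold (2.50 to 2.73) lower. Mitosis genes had a median of -0.53 (percentile 0, 4 of 11 lower), with Cdk1 3.11-fold (2.86 to 3.38) lower, but the median was 0.12 for the mean of CPM per barcode and 0.071 for thinned barcodes. Nuclear genes of the respiratory chain had a median of -0.26 (percentile 0.12), with Sdhd, a subunit of succinate dehydrogenase, 2.95-fold (2.81 to 3.10) lower and cytochrome c (Cycs) 2.00-fold lower. ER chaperones (-0.30, percentile 0.28, with Sdf2l1 2.56-fold lower), heat shock genes (-0.35, percentile 1.96, with Hsph1 1.83-fold lower) and erythroid markers (-1.33, percentile 0, with Hbb-bt 2.55-fold lower) lay below the random lists. The erythroid median was the ratio of Hbb-bt itself, with Hbb-bs at -1.41 and Blvrb at -0.0997. Reads of the near-identical copies Hbb-bs and Hbb-bt could be split, so this median does not show a change of erythroid genes at large. HSC ageing genes had a median of -0.15 (percentile 0.51), with 7 of 34 lower and 4 of 34 higher, and with Sbspon 2.56-fold (2.44 to 2.68) and the von Willebrand factor gene Vwf 1.72-fold (1.65 to 1.78) lower.

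Mitochondrially encoded mRNA was higher with ConA than in the untreated library (12 of 13 members, median 1.16, percentile 100), with mt-Nd6 6.20-fold (5.93 to 6.49) and mt-Nd5 3.38-fold (3.32 to 3.44) higher. These mRNAs made up 1.66% of kept UMIs in the untreated library and 3.07% to 3.72% in the other 5. Other genes with the highest ratios were Ulk4 at 70.7 against 3.29 CPM, Ccdc152 at 18.8 against 0.702 CPM, lymphotoxin beta (Ltb) at 234 against 43.0 CPM, Cd53 at 40.1 against 8.31 CPM, Serpina3f at 14.0 against 2.24 CPM and platelet factor 4 (Pf4) at 130.5 against 30.3 CPM. Genes with the lowest ratios were Igkc at 0.72 against 43.3 CPM, Ighg1, at least 647-fold lower, Rasl11a at 3.36 against 26.5 CPM, Nutf2-ps1 at 3.13 against 18.0 CPM, and the histone genes Hist1h2ab, Hist1h3c, Hist1h3f and Hist1h2ap, 9.18-fold, 8.76-fold, 6.77-fold and 4.62-fold lower.

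With ConA 193 genes were at least 2-fold higher and 106 at least 2-fold lower among 8682, so 64.6% of these were higher, and 136 against 140 under median-of-ratios scaling, or 49.3%. Over the DMSO library 177 were higher and 345 lower, or 33.9% higher. Ratios against the DMSO library, treated as young, hold the age difference as well. There the medians of HSC ageing genes (1.59), erythroid markers (0.18) and interferon response genes (-0.68) had the opposite sign, as had Pf4 (-0.61), and mitochondrially encoded mRNA stood at 0.061.

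The ddC comparison asked the same for blocked replication of mitochondrial DNA, again against the untreated library. Immediate early genes were higher (8 of 11 members, median 0.90, percentile 100), with Egr1 11.5-fold (11.1 to 11.9), Fos 14.3-fold (12.1 to 16.9), Klf2 4.69-fold (4.21 to 5.24) and Ier2 3.33-fold (3.23 to 3.43) higher. Mitosis genes were higher (12 of 17 members, median 0.88, percentile 100), with the kinetochore gene Cenpf 2.24-fold (2.09 to 2.41), Nusap1 2.27-fold and the checkpoint kinase Bub1b 2.34-fold higher. Mitochondrially encoded mRNA was higher (12 of 13 members, median 0.95, percentile 100), with mt-Nd6 4.86-fold (4.63 to 5.09) and mt-Nd5 3.76-fold (3.70 to 3.83) higher, against the low level of the untreated library given above. Genes that maintain mitochondrial DNA did not stand apart in this or any other comparison (medians from -0.096 to 0.13).

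HSC markers had a median of 0.31 (percentile 97.8), with the transcription factors Mecom 1.90-fold (1.86 to 1.95) and Meis1 1.52-fold (1.48 to 1.55) higher. Class I antigen presentation genes had a median of -0.21 (percentile 0.84, 6 of 14 lower), with B2m 2.02-fold (2.00 to 2.04) and H2-T23 2.42-fold (2.37 to 2.48) lower. Nuclear respiratory chain genes (-0.15, percentile 0.71) included Sdhd, 2.92-fold (2.77 to 3.09) lower, and Ndufa1, 1.97-fold lower. V-ATPase subunits (-0.17, percentile 0.66, with Atp6ap2 1.48-fold lower) and lysosomal hydrolases (-0.077, percentile 1.35, with Arsa 1.42-fold lower) had no member 1.5-fold apart. ER chaperones (-0.20, percentile 0.39, with Sdf2l1 2.26-fold lower) and erythroid markers (-0.36, percentile 1.68, with Hbb-bs 1.55-fold lower) also lay below the random lists. The erythroid median was again the ratio of Hbb-bt, with Blvrb at -0.145. HSC ageing genes had a median of -0.15 (percentile 0), with 2 of 32 lower and 0 higher by 1.5-fold, Sbspon 1.64-fold and Plscr2 1.55-fold lower.

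Other genes with the highest ratios under ddC were Ighm at 15.5 against 0.039 CPM, Ulk4 at 36.6 against 3.29 CPM, Ccdc152 at 12.5 against 0.702 CPM and Pf4 at 191 against 30.3 CPM. The lowest ratios were those of Ighg1, at least 452-fold lower, Hist1h2ac, 7.504-fold lower, Nutf2-ps1, 7.99-fold, Rpa3, a subunit of the single-stranded DNA binding complex, 4.86-fold (4.49 to 5.26), Rnaset2a and Rnaset2b, 4.25-fold and 3.81-fold, and Bloc1s1, 3.65-fold (3.44 to 3.87) lower. With ddC 77 genes were at least 2-fold higher and 73 at least 2-fold lower among 8673, so 51.3% were higher, and 45 against 105 under median-of-ratios scaling, or 30%, and 192 against 74 for thinned barcodes, or 72.2%. Against the DMSO library, which also differs in age, the medians of HSC ageing genes (1.61), mitosis genes (-1.02), lysosomal hydrolases (0.077), V-ATPase subunits (0.0012), erythroid markers (0.31) and mitochondrially encoded mRNA (-0.046) had the opposite sign, as had the log2 ratios of Ulk4 (-0.21) and Pf4 (-0.059).

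Set directly against ddC, without the shared untreated library, the ConA library had higher cholesterol synthesis genes (17 of 24 members, median 0.73, percentile 100). The ConA and ddC libraries also differed in kept barcodes (30780 and 7859) and in their median UMIs (2130 and 5089). A drug effect and a difference between libraries cannot be told apart here either. Insig1 was 2.29-fold (2.22 to 2.36) and Mvd 2.24-fold (2.11 to 2.38) higher. P53 targets (median 0.65, percentile 100, 8 of 14 higher), NF-kB targets (0.61, percentile 100, 6 of 11 higher) and interferon response genes (0.45, percentile 100, 12 of 31 higher) were also higher. Gdf15, a stress-induced cytokine, stood at 166 against 24.1 CPM, 6.91-fold (6.53 to 7.31) higher, and Phlda3, Nfkb2 and Ifit1 were 2.77-fold, 3.02-fold and 3.01-fold higher. V-ATPase subunits (0.28, percentile 100), lysosomal membrane proteins (0.28, percentile 100) and lysosomal hydrolases (0.23, percentile 100) all lay above the random lists, with the pump subunit Atp6v0a1 1.53-fold (1.43 to 1.64) and the protease Ctss 2.27-fold (1.99 to 2.59) higher. Against the untreated library, V-ATPase subunits and hydrolases lay below the random lists with ddC and did not stand apart with ConA. Autophagy genes (0.22, percentile 99.99) included Sqstm1, 1.71-fold (1.65 to 1.77) higher.

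Mitosis genes were lower with ConA than with ddC (16 of 17 members, median -1.38, percentile 0), with Cenpf 4.74-fold (4.32 to 5.20) and Ube2c 3.74-fold (3.41 to 4.11) lower. Replication genes (-0.71, percentile 0, 17 of 23 lower) included Clspn, 2.55-fold lower, and ribosome biogenesis and Myc targets (-0.52, percentile 0) included Nolc1, 1.92-fold lower. Erythroid markers (-0.79, percentile 0.09, the ratio of Hbb-bs itself) and heat shock genes (-0.25, percentile 2.48, with Hsph1 1.80-fold lower) were below the random lists. Hypoxia response (0.30, percentile 99.99, with Ddit4 1.84-fold higher), class I antigen presentation (0.24, percentile 99.96), immediate early (0.48, percentile 100, with Junb 1.82-fold higher) and quiescence genes (0.19, percentile 99.6, with Btg1 1.67-fold higher) were above them. Ltb, Cd53, Rgs1 and Serpina3f were 3.89-fold, 3.25-fold, 3.09-fold and 3.55-fold higher, and Igkc, Ighm, Hist1h3c and Hist1h1b 42.0-fold, 96.2-fold, 7.42-fold and 4.64-fold lower. In all 45 genes were at least 2-fold higher and 91 at least 2-fold lower among 8743, against 101 and 106 for barcodes of at least 10000 UMIs and 20 and 17 among genes of at least 50 CPM.

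Across 8441 genes the ConA and ddC log2 ratios had Pearson's r of 0.681 and Spearman's rho of 0.665, where genes are not independent replicates. Both ratios share the untreated library, and 20 simulations of unchanged groups gave a mean r of 0.467 and at most 0.481. The covariance was 0.108 against 0.000898 in those simulations. Of 8512 genes in both comparisons, 163 were at least 2-fold higher with ConA and 69 with ddC, and 45 of them were shared, where independent lists would share 1.32. At least 2-fold lower were 106 and 73, with 45 shared against 0.909. The simulations held counting error only. Any other deviation of the shared untreated library would also raise r, covariance and overlap. Part or all of the excess may therefore come from this control, and a response shared by both drugs cannot be told apart.

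Culture of old HSCs for 16 h, untreated over fresh, asked what the culture time itself changes. Immediate early genes were lower after culture (14 of 15 members, median -2.94, percentile 0), with Fos 152-fold (129.6 to 179), Fosb 47.0-fold (40.4 to 54.9) and Dusp1 22.8-fold (20.6 to 25.2) lower. Megakaryocyte markers were lower (9 of 10 members, median -2.52, percentile 0), with Pf4 at 30.3 against 2905 CPM. Cholesterol synthesis genes were higher (22 of 24 members, median 1.67, percentile 100), with Fdps 6.88-fold (6.67 to 7.09) and Mvd 7.67-fold (6.90 to 8.54) higher. Lysosomal hydrolases were higher (19 of 25 members, median 0.82, percentile 100), with the protease Ctsd 4.71-fold (4.61 to 4.80) higher. Id3, an inhibitor of helix-loop-helix transcription factors, stood at 241 against 0.519 CPM, and its relative Id1 was 24.1-fold (22.2 to 26.1) higher.

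In the same comparison V-ATPase subunits had a median of 0.65 (percentile 100, 9 of 16 higher) and lysosomal membrane proteins 0.45 (percentile 99.8), with Atp6ap2 1.87-fold and Cd63 3.63-fold higher. Iron handling genes (1.00, percentile 100, with Hmox1 10.7-fold higher), p53 targets (0.83, percentile 100, with Phlda3 10.7-fold higher), glycolysis genes (0.71, percentile 100, with Pkm 2.03-fold higher) and cytokine signalling targets (0.66, percentile 99.99, with Cish 5.46-fold higher) were above the random lists. So were ribosome biogenesis and Myc targets (0.42, percentile 99.4) and nuclear respiratory chain genes (0.32, percentile 98.9). Mitosis genes were lower in 21 of 21 members (median -1.94, percentile 0), with Ube2c 8.33-fold lower, and mitochondrially encoded mRNA in 13 of 13 (median -1.05, percentile 0). The untreated library was also lower in these mRNAs than each other cultured library, by medians of -0.95 to -1.16, so this is not read as a change with culture. Class II antigen presentation (-1.01, percentile 0.01, with Cd74 2.38-fold lower), interferon response (-0.36, percentile 0, with Iigp1 3.65-fold lower), quiescence (-0.29, percentile 0.8, with Txnip 3.07-fold lower), HSC marker (-0.28, percentile 0.33, with Esam 1.64-fold lower), HSC ageing (-0.20, percentile 0.01, with Gem 13.8-fold lower), ER chaperone (-0.15, percentile 2.22, with Hspa5 1.68-fold lower) and cytoplasmic ribosomal protein genes (-0.036, percentile 1.95) were below them.

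Other genes with the highest ratios were Ahnak2, 61.0-fold, the cytokine receptor chain gene Csf2rb, 47.1-fold, and Gdf15, 32.1-fold higher, and Ighg1, at least 990.4-fold higher. Ighm stood at 0.039 against 52.1 CPM and Car1, a red cell carbonic anhydrase, at 0.013 against 30.4 CPM. Among 8698 genes, 261 were at least 2-fold higher and 367 at least 2-fold lower. The HSC ageing median was 0.52 among genes of at least 50 CPM, and without 3 clusters of barcodes that of ER chaperones was 0.24 and that of mitosis genes -0.82.

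Culture of young HSCs, DMSO over young fresh, gave lower immediate early genes (14 of 15 members, median -2.29, percentile 0; Fosb 76.6-fold (65.4 to 90.3) and Nr4a1 58.3-fold (47.9 to 71.8) lower) and lower megakaryocyte markers (9 of 10 members, median -2.03, percentile 0). Pf4 stood at 199 against 2303 CPM. Cholesterol synthesis genes were higher (21 of 23 members, median 1.27, percentile 100), with Hmgcs1 4.78-fold (4.59 to 4.99) higher. Interferon response genes were higher (22 of 34 members, median 1.03, percentile 100), with Ifi27l2a 10.97-fold (10.1 to 11.9), Irf7, a transcription factor of this response, 9.26-fold (8.69 to 9.87) and Bst2 4.91-fold higher.

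Antigen presentation genes of class I (0.55, percentile 100, with H2-T22 2.14-fold higher) and class II (0.79, percentile 99.99, with Cd74 2.72-fold higher) were higher after culture of young cells. Lysosomal membrane proteins (0.59, percentile 100, with Cd68 3.89-fold higher), lysosomal hydrolases (0.57, percentile 100, with Ctss 7.30-fold higher) and V-ATPase subunits (0.48, percentile 99.99) were higher as well. Replication genes (0.55, percentile 100, with Rrm2 1.88-fold higher), cytokine signalling targets (0.89, percentile 100, with Socs2 3.07-fold higher), iron handling genes (0.58, percentile 99.7, with Ftl1 1.89-fold higher) and p53 targets (0.44, percentile 99.6, with Phlda3 3.59-fold higher) were above the random lists. Below them were granulocyte markers (-1.47, percentile 0, with S100a9 15.3-fold lower), mitosis genes (-0.42, percentile 0, with Mki67 1.80-fold lower) and ER chaperones (-0.30, percentile 0.01, with Hspa5 2.22-fold lower). HSC markers (-0.25, percentile 0.04), HSC ageing genes (-0.11, percentile 0.1, with Selp 5.08-fold lower), quiescence genes (-0.19, percentile 0.13, with Btg1 1.82-fold lower) and cytoplasmic ribosomal proteins (-0.17, percentile 0.03, with Rps27 2.17-fold lower) also lay below. The cluster of barcodes with granulocyte genes held 2.71% of young fresh and 0.652% of DMSO barcodes. The granulocyte median was smaller in size among barcodes of at least 10000 UMIs, as given in the closing section.

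The highest single ratios were those of Ahnak2, 53.7-fold, the calcium-binding protein gene S100a4, 22.9-fold, Id3, 30.6-fold, and Csf2rb2, 13.1-fold higher. Igkc stood at 0.026 against 149 CPM, Ighg1 at 0.013 against 47.8 CPM and Fos at 5.19 against 248 CPM. Of 8707 genes, 223 were at least 2-fold higher and 167 at least 2-fold lower, so 57.2% were higher, 46.1% under median-of-ratios scaling (172 and 201) and 44.4% with mitochondrial and ribosomal protein genes left out of the totals (200 and 251). Without 3 clusters of barcodes the medians of mitosis genes (0.15) and ER chaperones (0.10) had the opposite sign, and among genes of at least 50 CPM the HSC ageing median was -1.35. Across 8441 genes the log2 ratios of culture in old and young cells had r of 0.630 and rho of 0.575, and these comparisons share no library.

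Old over young cultured cells, untreated over DMSO, asked whether the age difference is also seen after culture. HSC ageing genes were higher in the old library (32 of 33 members, median 1.72, percentile 100), with Sbspon 58.0-fold (47.6 to 71.4), Rorb 20.0-fold (17.1 to 23.5), P-selectin (Selp) 17.4-fold (15.3 to 19.8) and the metallothionein Mt2 23.9-fold (19.3 to 29.9) higher. Interferon response genes were lower (27 of 34 members, median -1.09, percentile 0), with Ifi27l2a 29.4-fold (26.1 to 33.3) and Irf7 26.3-fold (23.9 to 29.1) lower. Mitosis genes were lower in 21 of 21 members (median -1.82, percentile 0), with Ube2c 5.13-fold (4.81 to 5.48) lower, and replication genes in 18 of 23 (median -0.80, percentile 0), with Rrm2 3.89-fold (3.62 to 4.18) lower.

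Mitochondrially encoded mRNA was lower in the untreated library here too (median -1.02, percentile 0), with mt-Nd6 5.40-fold lower. Immediate early genes (-0.39, percentile 0.8, with Egr1 2.77-fold lower) and class I antigen presentation genes (-0.24, percentile 0.67, with Nlrc5 1.70-fold lower) were below the random lists. Above them were erythroid markers (0.45, percentile 99.5, with Hbb-bs 3.15-fold higher), cytokine signalling targets (0.41, percentile 99.99, with Id1 4.43-fold higher), p53 targets (0.27, percentile 99.96, with Zmat3 2.08-fold higher) and HSC markers (0.12, percentile 98.8, with Slamf1, which encodes CD150, 2.07-fold higher; the median was -0.31 among genes of at least 50 CPM). So were cytoplasmic ribosomal proteins (0.19, percentile 99.3), glycolysis genes (0.12, percentile 98.1, with Pfkp 1.78-fold higher) and V-ATPase subunits (0.098, percentile 98.0, with Atp6v1a 1.42-fold higher). The erythroid median was the ratio of Blvrb, with Hbb-bt at 0.436. Lysosomal hydrolases had a median of 0.16 and a mean of -0.02 (percentile 100), and quiescence genes a median of 0.12 and a mean of -0.047 (percentile 97.8). Other extreme ratios were those of Igkc at 43.3 against 0.026 CPM, Ighg1 at 24.1 against 0.013 CPM, Id3 at 241 against 14.4 CPM, Plac8 at 2.00 against 93.8 CPM and Ctss at 2.85 against 61.3 CPM, and Mcpt8 had 0 UMIs in the untreated library, at least 450.3-fold lower.

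Of the 124 genes at least 2-fold higher with age in fresh cells, 91 had a ratio above 0 in cultured cells and 58 were at least 2-fold higher, with a median of 0.95. Their median was 0.062 with ConA and 0.040 with ddC, each against the untreated library. Of the 59 genes at least 2-fold lower with age in fresh cells, 38 had a ratio below 0 in cultured cells. Among these 59, 29 were at least 2-fold lower, with a median of -0.87. For all 8441 genes, 58.55% had the same sign in the fresh and cultured age ratios. Over 8441 genes the age ratios in cultured and fresh cells had r of 0.338 and rho of 0.1999. The ConA and fresh age ratios had r of 0.127 and rho of 0.176, with r of -0.027 for the mean of CPM per barcode and -0.022 for thinned barcodes. The ddC and fresh age ratios had r of 0.011 and rho of -0.028, with r of -0.134 for the mean of CPM per barcode and -0.122 for thinned barcodes. Against the DMSO library, treated as young, these r values were 0.416 for ConA and 0.386 for ddC. Those ratios set old cells against young ones, so age alone can raise r, and a drug effect cannot be told apart. In cultured cells 127 genes were at least 2-fold higher and 315 at least 2-fold lower with age among 8731, and the untreated and DMSO libraries differ in vehicle as well as age.

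**Figure D3:**
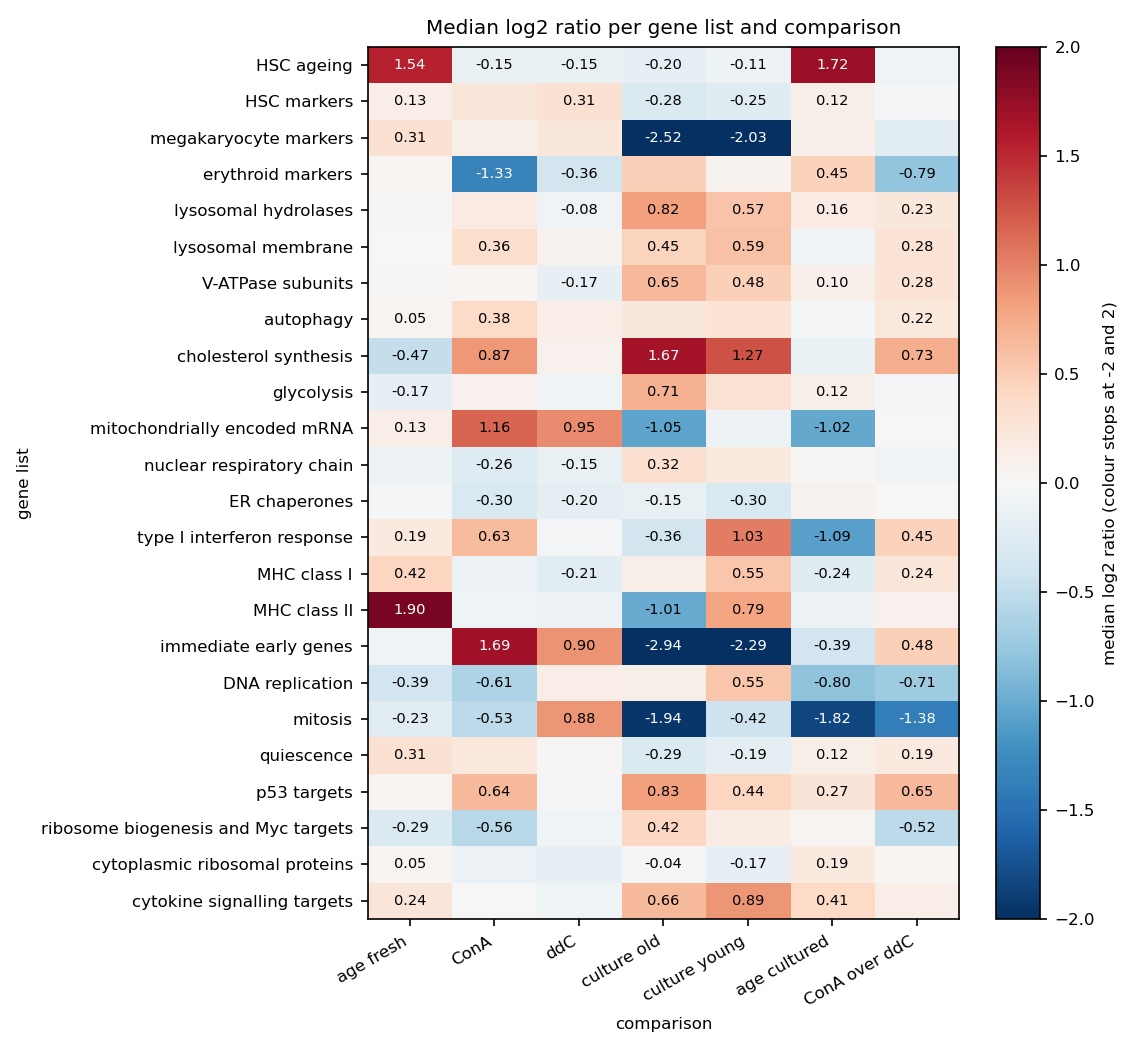
Median log2 ratio of each gene list that stood apart in at least 3 comparisons (vertical axis) in each of the 7 comparisons (horizontal axis), by colour. A value is printed only where the list stood apart, and the colour scale ends short of the most extreme medians. HSC ageing genes are at 1.54 in fresh and 1.72 in cultured cells and near 0 in the other comparisons, and immediate early genes are at -2.94 and -2.29 in the culture comparisons.

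**Figure D4:**
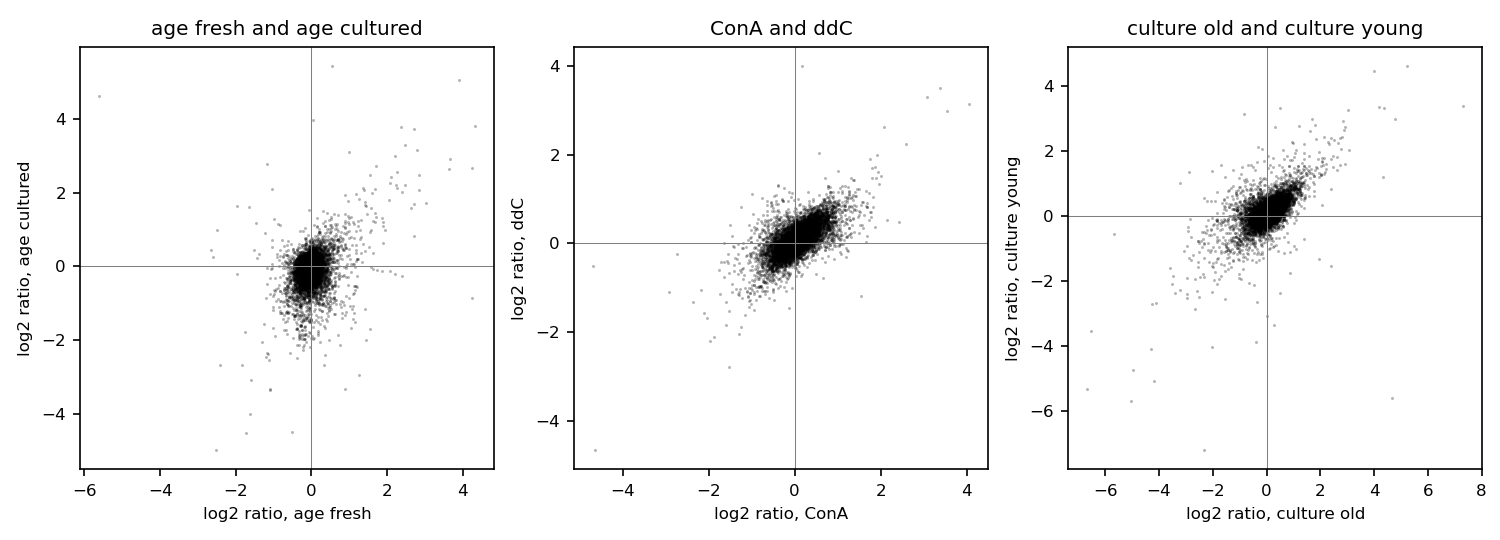
Log2 ratios of 8441 genes (points) in 3 pairs of comparisons, 1 per panel, with r of 0.338 for age in fresh and cultured cells, 0.681 for ConA and ddC and 0.630 for culture of old and young cells. Points spread along the rising diagonal most clearly in the ConA and ddC panel, whose axes share the untreated library.

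Kept barcodes of all 6 libraries were also clustered together. A megakaryocyte-like cluster, marked by Pf4, Treml1, Ppbp and Gp1bb, held 18.8% of kept barcodes in young fresh (exact binomial 95% interval 18.1 to 19.6), 34.3% in old fresh (33.7 to 34.9), 0.172% in DMSO, 0.147% in untreated, 0.382% in ddC and 0 of 30780 in ConA, which allows up to 0.012%. The intervals of these shares take barcodes as independent draws, although kept barcodes are not read as cells, so they may be too narrow. Car1, a red cell carbonic anhydrase, was also among the leading genes of the megakaryocyte-like cluster. At resolution 0.3, where most clusters followed single libraries, the cluster of that name held 19.2% of young fresh and 21136 of 21349 old fresh barcodes. At 1.0 the cluster of that name held 7.16% and 11.3%. An unnamed cluster there, led by the mitosis gene Ube2c and also marked by Pf4 and Ppbp, held 10.2% and 27.9%. A granulocyte-like cluster, marked by Elane, Mpo and Ctsg, held 2.71% (2.40 to 3.05) in young fresh, 0.276% (0.210 to 0.356) in old fresh and 0.652% (0.538 to 0.783) in DMSO, and no kept barcode of the other 3 libraries. At resolution 0.3 it held 80.7% of young fresh and 0.998% of old fresh barcodes. Most other barcodes fell into clusters filled largely from 1 library, such as those holding 77.6% of young fresh, 96.2% of DMSO and 96.4% of untreated barcodes, so the sizes of these clusters were not compared between groups. The sort excluded lineage-positive cells, and no cluster had 3 HSC markers among its leading genes.

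Lists with fewer than 3 members of at least 10 CPM in every comparison were those of lymphoid priming and of monocyte and macrophage, dendritic, B, T and NK, plasma, basophil and mast, eosinophil, endothelial and stromal cells. Mitochondrial chaperones and proteases (medians from -0.20 to 0.26), cGAS-STING pathway genes (-0.29 to 0.30) and NRF2 targets (-0.15 to 0.29) stood apart in none of the 7 comparisons. Values of histone genes, Hbb-bs and Hbb-bt, Rnaset2a and Rnaset2b, Serpina3f, Nutf2-ps1 and immunoglobulin genes are uncertain, since reads of near-identical copies could be split between them. Of the 306 named genes, 45 overlap a coding gene on the opposite strand in the annotation, among them Gpr183, Mab21l2, Ulk4, Ccdc152, Irf7, mt-Nd5 and mt-Nd6, and 18 overlap one on the same strand, among them Bloc1s1. The labels do not state whether counting used strand, so these values are uncertain too.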

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

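Chosen after the result they measure was seen were the tests of separate plasma cells, of evenly spread free RNA, of the 3 explanations for mitochondrial mRNA and of the age of the mice.

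Immunoglobulin transcripts lie outside the comparisons of HSC genes, yet barcodes rich in them (at least 20 such UMIs and 2% of the barcode) numbered 204 in old fresh, 63 in ddC and 35 in untreated, against 1 in young fresh and 0 in DMSO and ConA. In old fresh, all of the 98 with a variable gene call (100%) carried Igkv3-4, Igkv12-89, Ighv1-9 or Ighv1-55, which argues against many separate plasma cells, while clonally related plasma cells stay possible on this value alone. Variance over mean of immunoglobulin UMIs was 283.8 among barcodes of 1500 to 3000 UMIs, where free RNA spread evenly would stay below 2. HSC marker UMIs in these barcodes stood at 1.06 times the level in others of like depth (81 barcodes). RNA of 1 or more cells mixed into several droplets with RNA of HSCs may therefore account for the pattern in old fresh. Igkv3-4 led in 62 and Igkv12-89 in 20 of the 98 barcodes, so a single source cell is not shown. The HSC marker ratio was 0.844 in ddC (10 barcodes) and 0 in untreated (1 barcode). Igkc stood at 219 CPM and Jchain at 16.9 CPM in old fresh. Young fresh also held immunoglobulin RNA, with Igkc at 149 CPM and Ighg1 at 47.8 CPM. Its variance over mean among barcodes of 1500 to 3000 UMIs was 6.42, so the RNA was spread more evenly there. The lineage sort used B220, a B cell marker. An effect of age stays open, as untested.

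Mitochondrially encoded mRNA differed in direction between fresh and cultured age (0.13 and -1.02, a difference that was not tested) and was higher with both drugs than in the untreated library. Among barcodes of at least 10000 UMIs the lower of the ConA and ddC medians was 0.82. This floor kept 2669 untreated, 209 ConA and 1330 ddC barcodes and did not match their depth. It therefore cannot decide whether UMIs per barcode are the cause. The untreated library was lower than each of the other 5 by a median of -0.95 or less. In the same libraries 8 nuclear RNAs (7 in 1 pairing) had medians of -0.77 to -1.29. A property of the untreated library is therefore a candidate explanation. A property of the other 5, where barcodes of at least 500 UMIs outnumbered the sorted cells, would give the same values and was not tested. Among barcodes of at least 10000 UMIs, however, the nuclear medians were only -0.097 to -1.03. Against the DMSO library the higher of the ConA and ddC medians was 0.061 (0.39 among barcodes of at least 10000 UMIs), and a value below 0.5 had been set to exclude an effect of the drugs. That bound was wrong, since the DMSO library also differs in age, and a loss in culture of old cells that the drugs prevent would give the same value: a drug effect cannot be told apart here.

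Interferon response genes went opposite ways with culture, at -0.36 in old and 1.03 in young cells, and with age, at 0.19 in fresh and -1.09 in cultured cells, and these differences were not tested. Siglech, Ccr9, C1qa, C1qb and Adgre1, markers of plasmacytoid dendritic cells and macrophages, summed to 0.0110 of the excess of Irf7 in the DMSO library. On these markers the value argues against those cells. Ms4a6c, a monocyte and macrophage marker outside this sum, was among the leading genes of the cluster holding 96.2% of DMSO barcodes. Without the 5% of barcodes richest in interferon transcripts the median kept 0.899 of its value, so those barcodes alone do not carry it. Kept barcodes are not read as cells, so this value cannot tell whether the transcripts came from few or many cells. The young over old fresh median was -0.19, but this value is part of the pattern itself and does not show how age acts in culture, so an effect of age cannot be told apart. The DMSO vehicle and a property of this library stay open and untested as well, and the design confounds them with age.

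Class II antigen presentation genes had medians of -1.01 with culture in old cells and 0.79 in young cells, a difference that was not tested. Glycolysis genes had medians of -0.17 with age in fresh cells and 0.12 in cultured cells, which was not tested either. Class I antigen presentation genes had medians of 0.42 with age in fresh and -0.24 in cultured cells, again without a test of the difference.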

How the results depend on the processing

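Chosen after the data were seen were the settings that summed all barcodes, kept barcodes of at least 10000 UMIs or left out 3 clusters, marked as added. No paired analysis was possible because each group held 1 library and no test was run. In this part fresh age, cultured age, old culture and young culture name the comparisons. Over all settings 171 of 214 counts stayed within 1.5 times the main count and 43 did not. Of 1800 list medians 1651 stayed inside the interval from resampling members, 124 left it with the same sign and 25 changed sign. Of 78 correlations 53 stayed inside the interval from resampling genes, 16 moved and 9 changed sign, and of 24 cluster shares 14 stayed and 10 moved. Of 8157 ratios of named genes 4937 stayed inside their counting interval, widened where needed to hold the main ratio, 3181 left it and 39 changed sign. Of those that stayed, 535 each came from the minimums of 50 and 1 CPM, which leave a gene ratio unchanged. Another 535 came from the pseudocount of 0.1 CPM, which cannot move a ratio out of the widened interval. The outcome under these settings was fixed in advance and says nothing on stability. Mitochondrial limits of 10% and none moved no count, correlation or list median past these bounds. Median-of-ratios scaling moved the median of all genes from 0.064 to -0.044 with ConA, from 0.10 to -0.049 with ddC, from 0.14 to 0.013 in young culture and from -0.072 to 0.035 in cultured age, and totals without mitochondrial and ribosomal protein genes moved young culture to -0.0025. Removal of doublets gave no values, since scrublet called 2 barcodes in DMSO and 0 elsewhere, and no cluster met the naming rule for HSC-like, so that alternative was not run. Counts under a minimum of 50 or 1 CPM moved because fewer or more genes entered, and the DMSO control changes age, vehicle and library at once; otherwise the cause was not tested. Depth limits the ratio of a gene with 0 UMIs in a library to a bound, and 1 library per group limits every comparison.

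With the UMI floor at 20% of the percentile, the number of genes at least 2-fold higher was 46 for ddC. Pearson's r was 0.218 for cultured age with fresh age and 0.567 for old culture with young culture. Medians of lists were megakaryocyte markers 0.55, cholesterol synthesis -0.44, mitochondrially encoded mRNA 0.32, DNA replication -0.19, mitosis 0.051 and cytoplasmic ribosomal proteins -0.034 for fresh age. List medians stood at nuclear respiratory chain 0.24 for old culture, and granulocyte markers -1.10 and DNA replication 0.65 for young culture, and mitosis -1.90 for cultured age, and erythroid markers -1.03 and DNA replication -0.64 for ConA over ddC. Log2 ratios of genes were S100a8 0.068, Mki67 0.041 and Top2a 0.0064 for fresh age.

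With the UMI floor at 5% of the percentile, Pearson's r was 0.082 for ConA with fresh age and -0.049 for ddC with fresh age. By list, medians were DNA replication -0.50, mitosis -0.30 and cytoplasmic ribosomal proteins 0.088 for fresh age, and mitochondrially encoded mRNA 0.82 for ddC, and mitochondrially encoded mRNA -0.88 for old culture, and mitochondrially encoded mRNA -0.85 for cultured age.

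With mitochondrial and ribosomal protein genes left out of the totals, the number of genes at least 2-fold lower was 251 for young culture. The medians of lists were autophagy 0.11 and cytoplasmic ribosomal proteins 0.087 for fresh age, and nuclear respiratory chain -0.22 for ddC, and nuclear respiratory chain 0.24 and cytoplasmic ribosomal proteins -0.12 for old culture. Gene lists had medians of lysosomal hydrolases 0.44, DNA replication 0.42 and cytoplasmic ribosomal proteins -0.30 for young culture, and cytoplasmic ribosomal proteins 0.28 for cultured age.

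With the mean of CPM per barcode, the number of genes at least 2-fold higher was 135 for ddC. Correlations were -0.027 for ConA with fresh age, -0.134 for ddC with fresh age, 0.439 for cultured age with fresh age and 0.655 for ConA with ddC. Medians stood at HSC markers 0.082 and cytoplasmic ribosomal proteins 0.081 for fresh age, and nuclear respiratory chain -0.20, DNA replication -0.24, mitosis 0.12 and ribosome biogenesis and Myc targets -0.42 for ConA. Medians of lists were mitosis 1.41 for ddC, and nuclear respiratory chain 0.25 and mitosis -2.38 for old culture, and DNA replication -1.10 and mitosis -2.28 for cultured age. The log2 ratios were Birc5 0.041 for ConA.

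With thinned barcodes, the number of genes at least 2-fold higher was 192 for ddC. The r values were -0.022 for ConA with fresh age and -0.122 for ddC with fresh age. List medians stood at autophagy -0.055, cholesterol synthesis -0.57, DNA replication -0.47 and cytoplasmic ribosomal proteins 0.087 for fresh age. By list, medians were DNA replication -0.26, mitosis 0.071 and ribosome biogenesis and Myc targets -0.38 for ConA, and mitosis 1.44 for ddC, and nuclear respiratory chain 0.25 and mitosis -2.45 for old culture. The medians of lists were DNA replication -1.07 and mitosis -2.25 for cultured age. Log2 ratios of genes were Birc5 0.071 for ConA.

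With median-of-ratios scaling, the number of genes at least 2-fold higher was 45 for ddC. Gene lists had medians of cytoplasmic ribosomal proteins 0.078 for fresh age, and erythroid markers -1.44, nuclear respiratory chain -0.36 and ribosome biogenesis and Myc targets -0.66 for ConA. Medians stood at HSC ageing -0.30, lysosomal hydrolases -0.22, V-ATPase subunits -0.32, mitochondrially encoded mRNA 0.80 and nuclear respiratory chain -0.30 for ddC. Medians of lists were lysosomal hydrolases 0.46, DNA replication 0.43 and cytoplasmic ribosomal proteins -0.29 for young culture, and cytoplasmic ribosomal proteins 0.30 for cultured age.

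With a pseudocount of 0.1 CPM, medians were mitosis -1.88 for cultured age, and mitosis -1.50 for ConA over ddC.

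With a pseudocount of 5 CPM, the number of genes at least 2-fold higher was 117 for ConA, 41 for ddC and 27 for ConA over ddC. At least 2-fold lower were 38 for fresh age, 57 for ConA, 39 for ddC and 38 for ConA over ddC. Across genes r was -0.0094 for ddC with fresh age. List medians stood at cholesterol synthesis -0.43 for fresh age, and mitosis -1.61 for old culture, and lysosomal hydrolases 0.48 for young culture, and HSC ageing 1.34, erythroid markers 0.43 and mitosis -1.52 for cultured age. By list, medians were DNA replication -0.62 and mitosis -0.9952 for ConA over ddC.

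With a minimum of 50 CPM, the number of genes at least 2-fold higher was 36 for fresh age, 81 for ConA, 27 for ddC, 120 for old culture, 91 for young culture, 40 for cultured age and 20 for ConA over ddC. At least 2-fold lower were 13 for fresh age, 39 for ConA, 39 for ddC, 133 for old culture, 61 for young culture, 100 for cultured age and 17 for ConA over ddC. Pearson's r was -0.016 for ddC with fresh age, 0.241 for cultured age with fresh age and 0.73 for ConA with ddC. The medians of lists were autophagy 0.20 and type I interferon response 0.56 for fresh age, and lysosomal membrane 0.066 for ConA, and HSC ageing -0.23 for ddC. Gene lists had medians of HSC ageing 0.52, lysosomal membrane 0.80 and type I interferon response -0.61 for old culture. Medians stood at HSC ageing -1.35, megakaryocyte markers -0.97, lysosomal hydrolases 0.76 and lysosomal membrane 0.89 for young culture, and HSC ageing 2.02 and HSC markers -0.31 for cultured age.

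With a minimum of 1 CPM, the number of genes at least 2-fold higher was 233 for fresh age, 346 for ConA, 149 for ddC, 347 for young culture, 230 for cultured age and 82 for ConA over ddC. At least 2-fold lower were 113 for fresh age, 623 for old culture, 292 for young culture, 548 for cultured age and 145 for ConA over ddC. Correlations were -0.0023 for ddC with fresh age and 0.413 for cultured age with fresh age. Medians of lists were type I interferon response -0.056 for fresh age, and erythroid markers 0.20 for cultured age.

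With the DMSO library as control, the number of genes at least 2-fold higher was 128 for ddC. At least 2-fold lower were 345 for ConA and 164 for ddC. The r values were 0.416 for ConA with fresh age, 0.386 for ddC with fresh age and 0.768 for ConA with ddC. For the last, 20 simulations of unchanged groups sharing this control, with counting error only, gave a mean r of 0.468 and at most 0.484. List medians stood at HSC ageing 1.59, erythroid markers 0.18, lysosomal membrane 0.15, cholesterol synthesis 0.69, mitochondrially encoded mRNA 0.061 and type I interferon response -0.68 for ConA. By list, medians were DNA replication -1.44, mitosis -2.33 and p53 targets 1.15 for ConA. The medians of lists were HSC ageing 1.61, erythroid markers 0.31, lysosomal hydrolases 0.077, V-ATPase subunits 0.0012, mitochondrially encoded mRNA -0.046 and mitosis -1.02 for ddC. The log2 ratios were Pf4 -0.61, Igkc 0.75, Rasl11a 0.69, Sbspon 3.73, Ehd3 2.20 and Pygm 0.57 for ConA. Log2 ratios of genes were Vwf 1.18, Hbb-bs 0.18, Blvrb 0.35, mt-Nd2 -0.091, Irf7 -3.11 and Isg15 -1.16 for ConA. The log2 ratios were Bag3 0.41 for ConA. Log2 ratios of genes were Ulk4 -0.21, Pf4 -0.059, Sbspon 4.36, Plscr2 2.02, Ehd3 2.58 and Clu 1.54 for ddC. The log2 ratios were Hbb-bs 0.97, Hbb-bt 0.076, Blvrb 0.31, Ctsl 0.24 and Atp6v1a 0.11 for ddC. Log2 ratios of genes were mt-Nd6 -0.15, mt-Nd2 -0.022, Nusap1 -1.02, Cenpf -0.86, Bub1b -0.77 and Tpx2 -0.78 for ddC.

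With all barcodes summed (added), the number of genes at least 2-fold higher was 144 for ddC. Across genes r was 0.061 for ConA with fresh age, -0.053 for ddC with fresh age and 0.743 for ConA with ddC. Gene lists had medians of autophagy -0.011, cholesterol synthesis -0.55, DNA replication -0.49 and cytoplasmic ribosomal proteins 0.10 for fresh age, and mitochondrially encoded mRNA 0.78 and nuclear respiratory chain -0.25 for ddC. Medians stood at mitochondrially encoded mRNA -0.87, nuclear respiratory chain 0.40, ER chaperones 0.031 and mitosis -1.68 for old culture, and cytoplasmic ribosomal proteins -0.13 for young culture, and mitochondrially encoded mRNA -0.85 for cultured age. Medians of lists were DNA replication -0.64 for ConA over ddC.

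With barcodes of at least 10000 UMIs (added), the number of genes at least 2-fold higher was 39 for ddC and 101 for ConA over ddC. Pearson's r was 0.194 for ConA with fresh age and 0.527 for ConA with ddC. List medians stood at megakaryocyte markers 0.55, autophagy 0.14, cholesterol synthesis -0.43, mitochondrially encoded mRNA 0.40, DNA replication -0.21 and mitosis 0.0003 for fresh age. By list, medians were cytoplasmic ribosomal proteins -0.037 for fresh age, and mitochondrially encoded mRNA 1.36 and mitosis -0.76 for ConA, and mitochondrially encoded mRNA 0.82 and nuclear respiratory chain -0.072 for ddC, and nuclear respiratory chain 0.23 for old culture. The medians of lists were granulocyte markers -0.70 and lysosomal hydrolases 0.73 for young culture, and erythroid markers 0.33 for cultured age, and erythroid markers -0.9999, lysosomal membrane 0.37 and mitosis -1.67 for ConA over ddC. The log2 ratios were Mki67 0.015 for fresh age.

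With 3 clusters left out (added), Pearson's r was 0.197 for ConA with fresh age. Gene lists had medians of megakaryocyte markers 0.70, granulocyte markers 0.64, DNA replication -0.66, mitosis -0.86 and ribosome biogenesis and Myc targets -0.33 for fresh age. Medians stood at nuclear respiratory chain 0.52, ER chaperones 0.24, MHC class II -1.25, mitosis -0.82, ribosome biogenesis and Myc targets 0.50 and cytoplasmic ribosomal proteins -0.10 for old culture. Medians of lists were lysosomal hydrolases 0.48, ER chaperones 0.10, DNA replication 0.63 and mitosis 0.15 for young culture. Log2 ratios of genes were S100a8 0.46 for fresh age, and Sdf2l1 0.40 for young culture.

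With clustering at resolution 0.3, the shares were 99% for the megakaryocyte-like cluster in old fresh, 0.0858% for the megakaryocyte-like cluster in DMSO and 0.789% for the megakaryocyte-like cluster in ddC. Further shares were 80.7% for the granulocyte-like cluster in young fresh, 0.998% for the granulocyte-like cluster in old fresh and 0.154% for the granulocyte-like cluster in DMSO.

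With clustering at resolution 1.0, the shares were 7.16% for the megakaryocyte-like cluster in young fresh, 11.3% for the megakaryocyte-like cluster in old fresh and 0.0114% for the megakaryocyte-like cluster in DMSO. Further shares were 0.0636% for the megakaryocyte-like cluster in ddC.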

Other observations

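The genes and clusters in this part were chosen after their values were seen, and no test was run on them. Selp, an HSC ageing gene, stood at 17.3 CPM in young fresh, 93.5 in old fresh and 3.41 in DMSO, and at 59.2, 52.7 and 64.7 in untreated, ConA and ddC. Nupr1 stood at 28.5, 212 and 96.2 CPM in young fresh, old fresh and DMSO, and at 409.7, 340.1 and 324 in untreated, ConA and ddC. Gdf15, a stress-induced cytokine, stood at 3.25 and 1.74 CPM in young and old fresh, 41.1 in DMSO, 56.0 in untreated, 166.5 in ConA and 24.1 in ddC. Over the DMSO library the HSC ageing medians were 1.59 for ConA and 1.61 for ddC, and 101 and 93 of the 124 genes higher with age in fresh cells had ratios above 0. These ratios also hold the age difference between the libraries.

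A cluster marked by the stress genes Atf3, Egr4 and Hspb1 held 1.13% of kept barcodes in DMSO, 0.184% in untreated, 1.42% in ConA and 1.83% in ddC, and 0 in both fresh libraries, which allows up to 0.037% in young and 0.017% in old. At resolution 1.0 an erythroid-like cluster marked by Car1, Ermap and Klf1 held 1.34% of young fresh and 1.49% of old fresh barcodes.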
